A study of Rattus norvegicus with 6 samples.

How the data were processed

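Total RNA was extracted from freshly isolated rat islets with TRIzol and RNeasy columns, and libraries were made with a stranded total RNA kit that depletes ribosomal RNA (TruSeq with Ribo-Zero Gold), per the labels' protocols. Such a kit also keeps transcripts without a poly(A) tail. TopHat2 2.0.8b and edgeR 3.30.3 are named, per the submitters' processing notes, without a statement of their roles. The genome build, gene annotation, read counter and strand setting of the counting are not given in the sources used here, so overlapping and antisense genes cannot be separated with certainty.

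The authors deposited 1 table with a normalized expression signal per gene in 6 libraries, with no unit named in its header. The deposited signal is a whole number of reads multiplied by 1 constant per library. All of the values (100%) came out whole within a tolerance of 0.001 reads. The deposited columns sum to between 799845 and 1477540, and the library sizes implied by the constants, taking the unit as CPM, differ from the recovered reads by factors of 1.25, 1.09 and 1.06 for fetal replicates 1, 2 and 3 and 0.677, 1.03 and 0.992 for postnatal replicates 1, 2 and 3. TMM factors recomputed from the recovered reads gave the same 6 numbers to 3 digits. The signal is therefore treated as CPM of a TMM-scaled library size, called scaled CPM. Because postnatal replicate 1 has the smallest factor, 1 read is worth most there (0.0506 scaled CPM, against 0.0242 to 0.0344 in the others). The recovered depth was 26.1 to 37.8 M reads in the fetal and 28.2 to 29.5 M in the postnatal libraries, so 3 reads correspond to between 0.0726 and 0.152 scaled CPM. The table holds 18625 named genes, of which 16946 had a read in some library. A further row without a gene name held 1 to 9 reads per library, at most 3.19e-05% of a library. It was counted in the recovered reads and the recomputed factors, and left out of the tests. Gene symbols are those of the file, and older symbols in the lists were matched through a RefSeq table of the rat assembly GRCr8, used for names only. Of 662 list entries, 550 were matched and tested; genes such as Gapdh, Chga and H19 are not analysed here.

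Samples were grouped by title into fetal E19 and postnatal libraries, 3 each. Values were tested as log2(value + 1) with limma 3.58.1 in R 4.3.3 (trend on, robust off, group only), two-sided, over genes with a value of at least 1 in at least 3 libraries. P-values were adjusted by Benjamini-Hochberg and called under 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. Within a group, libraries differed by more than sampling noise (chi-square per degree of freedom 45.6 to 370), with Pearson r of the log2 values across genes of 0.983 to 0.987 among fetal and 0.970 to 0.988 among postnatal libraries, so none was counted as a duplicate. The design assumed normalized values, so the log-scale model stands as planned and count tests on the recovered reads serve as alternatives.

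The 27 gene lists, the main test, the rule for named genes and all alternatives except 2 were chosen before the data were examined. The rule named 10 fixed genes, the 5 largest rises and falls without overlap between groups and with a mean of at least 10 in the higher group, and the 2 largest changes of each list; other members are given as values of their list. Of the genes this rule picked, 4 are not reported here by name, though the counts and tests of their lists include them. List tests used camera with a preset correlation of 0.01, adjusted over 27 lists, beside camera with an estimated correlation and fry. Shares of reads were compared by a two-sided exact permutation test. Alternatives were pseudocounts of 0.1, 0.5 and 5, a looser and a stricter filter, 4 scalings, a robust trend, the replicate number as a block, the labelled week of age as a covariate, each library left out in turn, and edgeR 4.0.16 and DESeq2 1.42.0 on recovered reads. On simulated reads for this comparison (20 simulations with a median of 12779 genes, 200 of them changed), the test recovered a median of 50.7% of 2-fold changes (range 43.3% to 67.2%), 100% of 4-fold changes (lowest 97.0%) and 100% of 8-fold changes. The median share of false calls was 4.87%, with a range of 2.37% to 9.04%, so in some simulations it exceeded the 5% aimed at. The simulated reads held no shift in composition and no outlier library, whereas 63.1% of the genes tested were called in the real data. The simulated rates may therefore not hold there.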

Results

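RNA sequencing profiled pancreatic islets, the hormone-secreting cell clusters of the pancreas, from rats at embryonic day 19 (E19) and after birth, with 3 libraries per group. The comparison asks how the islet transcriptome differs between late fetal life and 2 weeks of age. The titles of the 3 postnatal libraries all give 2 weeks, whereas their age labels give postnatal weeks 2, 3 and 4 for replicates 1, 2 and 3. Libraries were grouped by title, and the later group is called postnatal. Gene expression is given as scaled CPM, counts scaled to a common library size after adjustment between libraries. The reads behind these values were 26.1, 37.8 and 30.7 M in fetal replicates 1, 2 and 3, and 29.2, 28.2 and 29.5 M in postnatal replicates 1, 2 and 3. Nothing in the labels says that replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical.

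The islet hormones took 0.450% ± 0.205 of the reads in the fetal libraries and 7.19% ± 3.53 in the postnatal ones (mean ± SD, n = 3 each). Transcripts of acinar cells, the enzyme-secreting cells around the islets, took 11.2% ± 1.68 and 33.4% ± 13.3. Postnatal replicate 1 had the highest acinar share, 48.7%, against 27.5% and 24.1% in postnatal replicates 2 and 3. Globin transcripts took 0.775% ± 0.438 of the fetal reads and 0.122% ± 0.0496 of the postnatal reads, and the mitochondrially encoded genes 1.43% ± 0.0600 and 1.15% ± 0.285. For hormones, acinar markers and globins the groups did not overlap, and the two-sided exact permutation test gave p = 0.1 for each, the smallest value that 3 libraries against 3 allow (0.125 after Benjamini-Hochberg adjustment over 5 shares). For the mitochondrially encoded genes the exact permutation p was 0.2. Wilson 95% intervals of the shares of single libraries reached at most 0.0182 percentage points from the share, and cover counting error only.

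**Figure D1:**
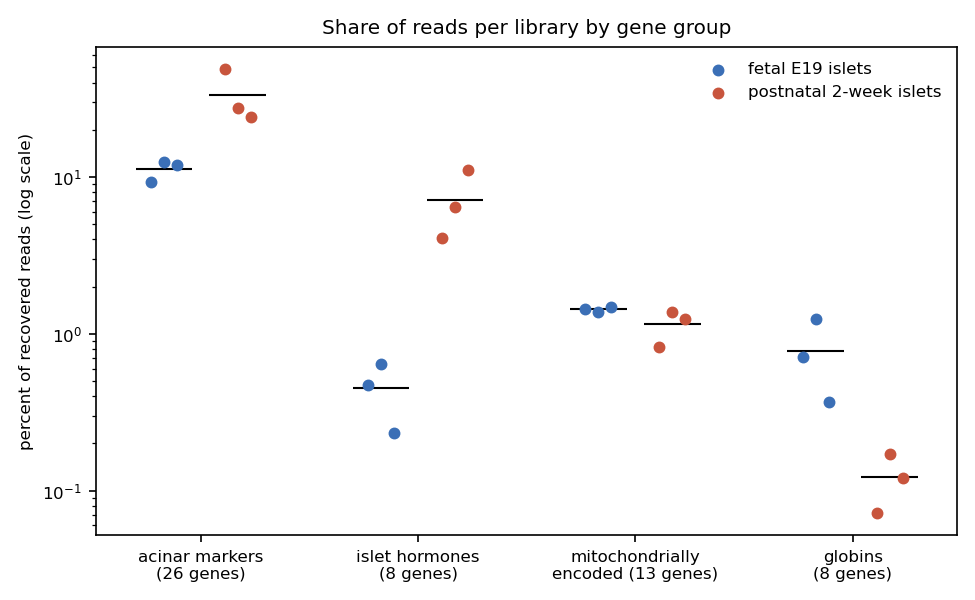
Percent of each library's recovered reads in acinar marker genes, islet hormone genes, mitochondrially encoded genes and globin genes on a logarithmic axis, with 1 point per library and bars at the group means. The acinar share lay between 9.28% and 12.4% in the fetal libraries and between 24.1% and 48.7% in the postnatal libraries, and the hormone share between 0.233% and 0.641% and between 4.07% and 11.0%.

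The fetal and postnatal islet preparations differed in 63.1% of the 12926 genes tested. Their acinar shares (11.2% and 33.4% of the reads) and hormone shares (0.450% and 7.19%) differed too. The count therefore does not separate changes within islet cells from a different mix of cells. Digestive enzyme genes showed the largest rises after birth, led by Pla2g1b, the pancreatic phospholipase A2, from 30.2 ± 41.4 to 7921 ± 5537 scaled CPM (mean ± SD, n = 3; log2 fold change 8.76 ± 0.95 SE). Cpb1, encoding pancreatic carboxypeptidase B, rose by 8.69 ± 1.01 on the log2 scale, and the trypsinogen genes Prss3b, Prss1 and Try5 by 8.43 ± 0.90, 8.01 ± 0.79 and 7.32 ± 1.71. The largest falls were those of Serpina6, encoding corticosteroid-binding globulin, from 221 ± 134 to 0.791 ± 0.253 (log2 fold change -6.76 ± 0.43), and of the fetal serum protein gene Afp (-6.36 ± 1.32). The embryonic globin gene Hbe1 fell by 5.98 ± 0.24. Dlk1, an imprinted gene of the Notch ligand family, fell by 4.70 ± 0.13.

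Of 12926 genes tested with limma, 3874 were higher and 4278 lower in the postnatal libraries at a Benjamini-Hochberg adjusted p under 0.05, together 63.1% of those tested. At least a 2-fold difference was present in 1916 of the higher and 1558 of the lower genes, and at least a 4-fold difference in 527 and 280. The 2-fold counts were 1115 and 1092 with a pseudocount of 5, and 2415 and 995 after rescaling without the 20 highest genes. That rescaling, in which most of the genes left out were digestive enzymes or hormones, moved the split of all calls to 5047 higher and 3222 lower, or from 47.5% to 61.0% higher, and the median of all tested genes from -0.03 to 0.20. Without fetal replicate 2 and postnatal replicate 1, which stood apart in liver and acinar transcripts and were chosen after the data were seen, 3786 genes were higher and 4089 lower. The 3 values of each group did not overlap in 9051 tested genes, 70.0% of them, where chance gives 10%. The first principal component held 86.7% of the variance and separated the groups, with fetal libraries between -71.8 and -52.4 and postnatal libraries between 47.0 and 66.6.

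Single libraries shaped the size of several of these changes, but leaving out any 1 of them ended none of these calls. Afp stood at 2792 in fetal replicate 2 against 60.6 and 87.6 in fetal replicates 1 and 3, and its log2 fold change was -4.62 without fetal replicate 2, -7.37 without fetal replicate 1 and -7.11 without fetal replicate 3. Try5 stood at 2330, 341 and 7.85 in postnatal replicates 1, 2 and 3, and its rise was 5.52 without postnatal replicate 1 and 9.54 without postnatal replicate 3. Without fetal replicate 1 the rises of Pla2g1b, Cpb1, Prss3b and Prss1 were 7.96, 7.63, 7.61 and 7.20, and without fetal replicate 2 they were 9.92, 9.84, 9.54 and 8.73. Prss1 rose by 7.42 without postnatal replicate 1. The postnatal values of Hbe1, 0 to 0.0688, lay under what 3 reads were worth (0.102 to 0.152), so its log2 value depends on the pseudocount. The trypsinogen genes and the alpha globin genes are near-identical families among which the counting could split reads, and their single values are uncertain for that reason.

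**Figure D2:**
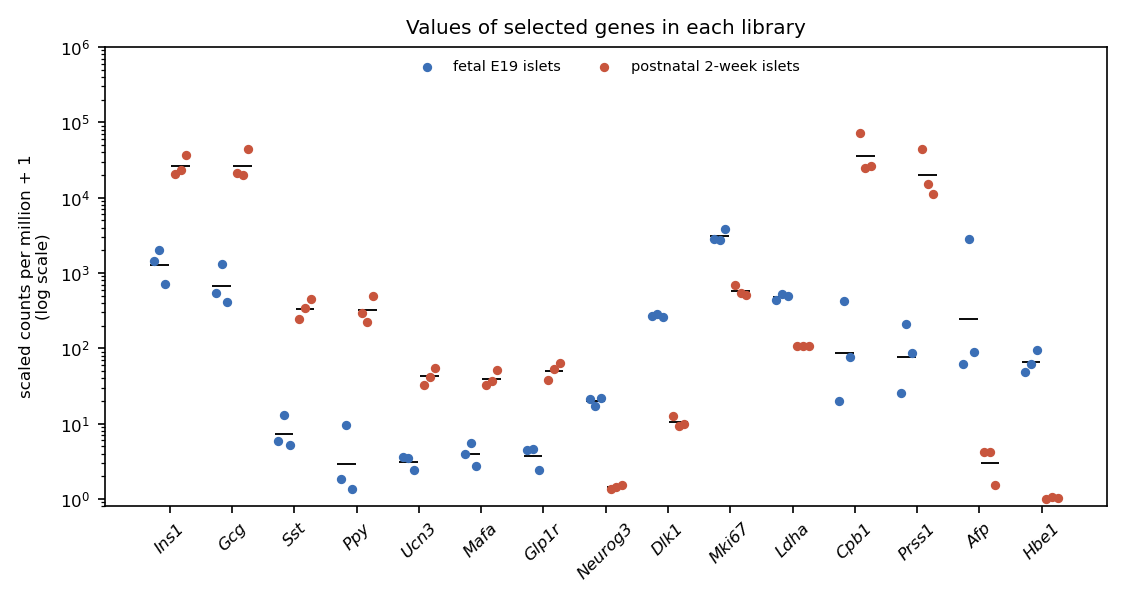
Scaled CPM plus 1 of selected genes in each library on a logarithmic axis, with fetal and postnatal libraries as separate points and bars at the geometric group means. The hormone genes Ins1, Gcg and Sst lay higher in every postnatal library than in any fetal library, and Neurog3, Mki67 and Ldha lower.

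Hormone genes rose strongly after birth. Ins1 rose from 1384 ± 646 to 26775 ± 8402 scaled CPM (log2 fold change 4.35 ± 0.49; adjusted p = 2.43e-04) and Ins2 from 1273 ± 596 to 19148 ± 5622 (3.99 ± 0.46). Gcg, encoding glucagon, rose from 757 ± 490 to 28372 ± 13466 (5.32 ± 0.53), and Sst, encoding somatostatin, from 6.96 ± 4.21 to 346 ± 103 (5.52 ± 0.36). Ppy, encoding pancreatic polypeptide, showed the largest rise of the list (6.79 ± 0.68, 7.65 without fetal replicate 2). Without both fetal replicate 2 and postnatal replicate 1, the rises of Gcg, Sst and Ppy were 5.97, 6.16 and 7.71. Of 18 hormone and granule genes, 13 rose and none fell, both over all genes tested and adjusted over the list alone. The risers included the prohormone convertases Pcsk1 (1.98 ± 0.24) and Pcsk2 (3.52 ± 0.30) and the amylin gene Iapp (3.19 ± 0.31). The 5 others did not pass: Chgb stood at 269 ± 38.0 and 332 ± 102, Ghrl at 20.2 ± 5.65 and 24.3 ± 1.97, Npy at 23.2 ± 7.66 and 21.7 ± 6.35, Pyy at 208 ± 47.4 and 158 ± 23.6, and Ttr at 56.1 ± 88.5 and 7.34 ± 2.26. The list was higher as a set by limma's camera with a preset correlation of 0.01 (median log2 fold change 3.17; adjusted p = 2.23e-05), but not when the correlation was estimated (adjusted p = 0.475 with an estimated correlation). Ins1 and Ins2 share long stretches of sequence, so the division of reads between them is uncertain.

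Beta cell maturity genes rose with the hormones, in libraries whose hormone share was 0.450% before and 7.19% after birth. Ucn3, encoding the peptide urocortin 3 of mature beta cells, rose from 2.15 ± 0.607 to 42.2 ± 11.5 (3.76 ± 0.23; adjusted p = 2.52e-05), and the transcription factor gene Mafa from 3.09 ± 1.43 to 39.1 ± 9.75 (3.33 ± 0.28; adjusted p = 7.05e-05). Glp1r, the receptor of the incretin GLP-1, rose by 3.78 ± 0.29. The glucose transporter gene Slc2a2 rose by 2.18 ± 0.27 and the granule zinc transporter gene Slc30a8 by 2.16 ± 0.23. Of 19 maturity genes, 18 rose, also 18 when adjusted over the list alone, and none fell; Nkx6-1 did not pass, at 22.6 ± 5.11 and 32.9 ± 12.5. The set was higher by camera (median 1.57; adjusted p = 8.02e-07), a call lost when the correlation was estimated (adjusted p = 0.470 with an estimated correlation).

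Genes of regulated secretion and of membrane excitability also rose. Syt4, encoding a synaptotagmin, rose from 1.47 ± 0.634 to 31.1 ± 8.55 (3.71 ± 0.25), and Cplx2, encoding the SNARE-binding protein complexin 2, by 2.19 ± 0.26. Among 28 exocytosis genes, 19 rose, 2 fell and 7 did not pass, and the counts were 19 and 2 when adjusted over the list alone. The 2 that fell were Cadps2 (-1.28 ± 0.21) and Stxbp2 (-0.59 ± 0.15). Casr, the calcium-sensing receptor gene, rose by 3.31 ± 0.24 and Atp2a3, a calcium pump gene of the endoplasmic reticulum, by 2.83 ± 0.28. Both subunit genes of the ATP-sensitive potassium channel rose, Kcnj11 by 2.24 ± 0.22 and Abcc8 by 1.75 ± 0.25. Of 27 channel and calcium handling genes, 23 rose and none fell, and 23 rose when adjusted over the list alone. Camera called both sets higher, with medians of 1.07 (adjusted p = 2.06e-04) and 1.08 (adjusted p = 2.41e-06). For each of them the call was lost when the correlation was estimated (adjusted p = 0.470 with an estimated correlation). The hormone share of the reads moved with both sets, from 0.450% to 7.19%.

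Genes of endocrine progenitors and islet development moved in both directions. Neurog3, the transcription factor that starts endocrine differentiation, fell from 19.0 ± 2.61 to 0.438 ± 0.0793 (-3.79 ± 0.15; adjusted p = 1.27e-05). Pax4 fell by 2.64 ± 0.14, Sox11 by 2.03 ± 0.22, Notch1 by 1.27 ± 0.22 and Hes6 by 1.07 ± 0.14, beside Dlk1. The endocrine transcription factor genes Neurod1 (1.74 ± 0.21), Pax6 (1.61 ± 0.22), Isl1 (1.26 ± 0.22) and Rfx6 (1.15 ± 0.18) rose. Of 21 genes in the list, 7 rose, 6 fell and 8 did not pass, with 7 and 6 when adjusted over the list alone. Camera made no call (adjusted p = 0.986), the median log2 fold change was 0.10 and the mean -0.32, and fry, which tests whether genes move on balance one way, pointed down (adjusted p = 0.00636).

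Genes that mature beta cells normally repress were split as well. Ldha, encoding lactate dehydrogenase A, fell from 486 ± 49.1 to 107 ± 0.532 (-2.16 ± 0.11; adjusted p = 1.68e-05), and Slc16a1, encoding the monocarboxylate transporter MCT1, fell by 1.71 ± 0.12. Hormones took 0.450% of the reads before and 7.19% after birth, and acinar markers 11.2% and 33.4%. The falls of Ldha and Slc16a1 therefore cannot be placed in beta cells. Cd302, a lectin receptor gene, rose from 2.01 ± 0.871 to 10.4 ± 3.03 (1.92 ± 0.27). The other risers included Pdgfra (1.26 ± 0.15), a fibroblast receptor, and Cxcl12 (1.35 ± 0.21), a stromal chemokine, in libraries whose mesenchymal markers rose by a median of 1.51. Of 20 genes, 9 rose, 7 fell and 4 did not pass, and 9 and 7 when adjusted over the list alone. Camera made no call (adjusted p = 0.580); the median was 0.39 and the mean 0.18, while fry pointed down without passing (adjusted p = 0.606).

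Proliferation genes fell without exception among those tested. Mki67, the proliferation marker Ki-67, fell from 3119 ± 581 to 575 ± 91.6 scaled CPM (-2.43 ± 0.21; adjusted p = 8.16e-05). Birc5, encoding survivin, fell by 2.98 ± 0.13 and the spindle checkpoint kinase gene Bub1b by 2.89 ± 0.11. All 32 genes of the list fell, also when adjusted over the list alone, from Gins2 (-0.58 ± 0.11) to Birc5. The set was lower by camera (median -2.33; adjusted p = 2.07e-15), a call lost when the correlation was estimated (adjusted p = 0.470 with an estimated correlation). In the same libraries erythroid markers fell by a median of 2.16, and the acinar share of the reads was 11.2% before and 33.4% after birth. Among 6 D-type cyclin and CDK inhibitor genes, 4 rose, 1 fell and 1 did not pass, and the counts were 4 and 1 when adjusted over the list alone. The inhibitor gene Cdkn2c rose by 1.01 ± 0.13 and the cyclin gene Ccnd1 by 0.88 ± 0.09, while Ccnd3 fell by 0.78 ± 0.09 (camera adjusted p = 0.146).

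Oncofetal and imprinted growth genes fell in the main. Igf2, encoding insulin-like growth factor 2, fell from 1467 ± 162 to 171 ± 29.5 (-3.10 ± 0.16), Igf2bp1, encoding an RNA-binding protein of fetal tissues, by 3.50 ± 0.20, and Dlk1 from 271 ± 13.2 to 9.53 ± 1.77. Of 15 genes, 13 fell, both over all genes and adjusted over the list alone, in libraries whose erythroid markers fell by a median of 2.16. The 2 that rose were Slc38a4, encoding an amino acid transporter (2.36 ± 0.20), and Gnas, encoding the stimulatory G protein alpha subunit (0.40 ± 0.15). Camera called the set lower (median -1.97; adjusted p = 7.39e-05), and the call was lost with an estimated correlation (adjusted p = 0.307 with an estimated correlation).

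Nuclear genes of mitochondrial respiration and the tricarboxylic acid cycle fell after birth. Atp5f1b, encoding the ATP synthase beta subunit, fell from 2069 ± 262 to 720 ± 113 (-1.52 ± 0.19) and Cyc1, encoding cytochrome c1, from 152 ± 18.9 to 59.0 ± 9.52 (-1.36 ± 0.14). Of 43 nuclear-encoded oxidative phosphorylation genes, 42 fell and none rose, with 42 when adjusted over the list alone; Ndufa1 did not pass. Suclg2 and Sdhd, subunits of succinyl-CoA synthetase and succinate dehydrogenase, fell by 1.18 ± 0.18 and 1.14 ± 0.14. Of 25 tricarboxylic acid cycle and pyruvate entry genes, 19 fell and 2 rose, with 20 falling when adjusted over the list alone. In the same libraries the acinar share of the reads went from 11.2% to 33.4%. Cytosolic ribosomal protein genes, grouped by symbol after their values were seen and with like-named genes included, fell in 76 of 77 cases (median -1.05). After rescaling without the 20 highest genes the medians were -0.69 for respiration and -0.49 for the cycle, with 39 and 18 genes falling. Camera called the respiration set (median -0.93; adjusted p = 6.01e-09) and the cycle set (median -0.73; adjusted p = 2.06e-04) lower. Both camera calls were lost when the correlation was estimated: for respiration adjusted p = 0.475 with an estimated correlation, and for the cycle adjusted p = 0.477 with an estimated correlation. Among the 13 mitochondrially encoded genes 1 fell, Mt-atp8 (-0.35 ± 0.13; adjusted p = 0.0441), and adjusted over the list alone none did. The Mt-atp8 call ended under 10 of the 22 alternatives that tested single genes, with adjusted p up to 0.455 after rescaling without the 20 highest genes. The median of these 13 genes was -0.05 (camera adjusted p = 0.726), and 0.19 after that rescaling, when 3 rose and none fell. Without fetal replicate 2 and postnatal replicate 1 it was -0.30, when none rose and 5 fell, and with the labelled week of age as a covariate -0.03, when 2 rose and none fell.

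Glycolytic genes moved both ways, and genes of cholesterol synthesis fell throughout the list. Tpi1, encoding triosephosphate isomerase, fell from 488 ± 47.9 to 118 ± 6.90 (-2.04 ± 0.11), while the neuroendocrine enolase gene Eno2 rose by 2.03 ± 0.22. Of 13 glycolysis genes, 7 fell, 3 rose and 3 did not pass, with 7 and 3 when adjusted over the list alone (median -0.68; camera adjusted p = 0.0659). Dhcr7, encoding the last enzyme of one branch of cholesterol synthesis, fell from 132 ± 13.7 to 18.4 ± 4.86 (-2.80 ± 0.18). All 23 genes of the cholesterol list fell, and 23 fell when adjusted over the list alone, while the acinar share went from 11.2% to 33.4%. Camera called the set lower (median -1.86; adjusted p = 9.03e-10), and the call was lost when the correlation was estimated (adjusted p = 0.470 with an estimated correlation).

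Among genes of fatty acid oxidation and ketogenesis, Pdk4, a kinase that inhibits pyruvate dehydrogenase, rose from 10.6 ± 1.87 to 75.1 ± 31.4 (2.63 ± 0.31). Acads, a short-chain acyl-CoA dehydrogenase gene, fell by 1.15 ± 0.13. Of the 25 genes, 5 rose, 13 fell and 7 did not pass, and 14 fell when adjusted over the list alone (median -0.41; camera adjusted p = 0.267). After rescaling without the 20 highest genes, 8 of them rose and 8 fell. Of 25 genes of protein folding and stress in the endoplasmic reticulum, 5 rose and 9 fell, with 5 and 9 when adjusted over the list alone. The 2 stress-responsive genes Ppp1r15a and Dnajb9 rose by 1.51 ± 0.31 and 1.47 ± 0.11, while the chaperone genes Hspa5 and Hsp90b1 fell by 0.68 ± 0.20 and 1.09 ± 0.19. The list's median was -0.07 (camera adjusted p = 0.771) and 0.17 after that rescaling.

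Circadian clock genes rose as a group. Bhlhe41, encoding the repressor DEC2, rose from 1.01 ± 0.271 to 11.0 ± 2.81 (2.56 ± 0.20), and Nr1d2, encoding the nuclear receptor REV-ERB beta, from 9.17 ± 1.46 to 57.7 ± 1.40 (2.54 ± 0.13). Arntl, encoding BMAL1, rose by 1.30 ± 0.17, and Cry1 fell by 0.97 ± 0.10. Of 19 clock genes, 16 rose, 1 fell and 2 did not pass, with 16 and 1 when adjusted over the list alone. Camera called the set higher (median 1.17; adjusted p = 1.32e-05), a call lost when the correlation was estimated (adjusted p = 0.415 with an estimated correlation). The time of day of collection is not given in the sources used here. In the same libraries mesenchymal and endothelial markers rose by medians of 1.51 and 1.38.

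Interferon response and antigen presentation genes rose in the main. The transcription factor gene Irf1 rose from 17.9 ± 4.59 to 166 ± 75.5 (3.05 ± 0.36) and the class I MHC gene RT1-A1 from 28.6 ± 5.45 to 173 ± 46.8 (2.53 ± 0.22). B2m, encoding the class I light chain, rose by 2.12 ± 0.24. Of 26 genes, 19 rose, 2 fell and 5 did not pass, with 19 and 2 when adjusted over the list alone; the 2 that fell were the interferon-induced genes Mx2 (-0.96 ± 0.22) and Ifit1 (-1.49 ± 0.41). Camera called the set higher (median 1.17; adjusted p = 1.26e-05), and the call was lost when the correlation was estimated (adjusted p = 0.475 with an estimated correlation). Class I MHC genes of the rat are a family of close copies, so RT1-A1 is uncertain as a single gene. Macrophage and myeloid markers moved in the same direction in these libraries, with a median of 1.01.

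Acinar markers rose, but not alike. Besides Cpb1 and Prss1, Cel, encoding bile salt-stimulated lipase, rose by 3.70 ± 0.73, while Ptf1a, an acinar and progenitor transcription factor gene, fell from 257 ± 78.0 to 28.6 ± 12.6 (-3.16 ± 0.31). Named after their values were seen, the most abundant fetal enzyme genes did not pass: Pnliprp1 stood at 35380 ± 8365 and 87281 ± 57653, Ctrb1 at 25276 ± 5751 and 51022 ± 33712, and Cpa1 at 19034 ± 4098 and 28579 ± 16390. Of 26 acinar markers, 20 rose, 1 fell and 5 did not pass, with 20 and 1 when adjusted over the list alone. Camera called the set higher (median 3.40; adjusted p = 1.32e-05), a call lost when the correlation was estimated (adjusted p = 0.475 with an estimated correlation). Of 14 duct markers, 7 fell and none rose, with 7 when adjusted over the list alone (median -0.78; camera adjusted p = 0.112). Krt19, a duct keratin gene, fell from 67.9 ± 12.6 to 25.5 ± 0.397 (-1.36 ± 0.13), and Muc1 by 1.34 ± 0.35.

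Stromal and vascular markers rose. Rgs5, a pericyte gene, rose from 3.66 ± 1.26 to 56.9 ± 10.5 (3.65 ± 0.22) and the matrix proteoglycan gene Lum from 20.7 ± 14.2 to 185 ± 37.4 (3.28 ± 0.40). Of 20 mesenchymal and stellate cell markers, 18 rose and none fell, with 18 when adjusted over the list alone. Vwf, encoding von Willebrand factor, rose from 11.5 ± 8.02 to 91.6 ± 35.2 (2.99 ± 0.45, and 3.84 without fetal replicate 2 and postnatal replicate 1), and Plvap, a gene of fenestrated endothelium, by 2.45 ± 0.18. All 18 endothelial markers rose, also when adjusted over the list alone. Camera called the mesenchymal set (median 1.51; adjusted p = 4.16e-07) and the endothelial set (median 1.38; adjusted p = 2.48e-06) higher. For each of them the call was lost when the correlation was estimated (adjusted p = 0.475 with an estimated correlation).

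Adipocyte markers rose too, with Fabp4, a fatty acid binding protein gene, going from 15.1 ± 6.83 to 162 ± 92.9 (3.25 ± 0.49) and the adipokine gene Adipoq from 0.303 ± 0.194 to 12.2 ± 8.76 (3.04 ± 0.56). Adipoq rose by 3.76 without postnatal replicate 1, and without fetal replicate 2 and postnatal replicate 1 the rises of Fabp4 and Adipoq were 4.05 and 3.87. Of 9 adipocyte markers, 8 rose and none fell, with 8 when adjusted over the list alone. The set was higher by camera (median 2.30; adjusted p = 0.00234) but not when the correlation was estimated (adjusted p = 0.475 with an estimated correlation) or with a filter on low values 5 times as strict (adjusted p = 0.166). Of 12 Schwann and neural markers, 7 rose, 3 fell and 2 did not pass, with 8 rising when adjusted over the list alone (median 0.78; camera adjusted p = 0.141). The glial cadherin gene Cdh19 rose by 1.89 ± 0.28, while Ret, Erbb3 and Gfap fell by 1.11 ± 0.13, 1.01 ± 0.17 and 1.73 ± 0.17.

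Markers of blood cells moved apart. Cd74 and RT1-Da, genes of class II antigen presentation, rose by 2.90 ± 0.50 and 2.81 ± 0.55. RT1-Da rose by 2.15 without postnatal replicate 2 and by 3.50 without fetal replicate 2 and postnatal replicate 1. Of 23 macrophage and myeloid markers, 11 rose, none fell and 12 did not pass, with 11 when adjusted over the list alone. The number that rose was 18 without fetal replicate 2 and postnatal replicate 1. It was 5 with the labelled week of age as a covariate, which estimates the difference at labelled week 2, with 1 library per week. Camera called the set higher (median 1.01; adjusted p = 0.00119), a call lost when the correlation was estimated (adjusted p = 0.581 with an estimated correlation). Erythroid markers fell in 15 of 16 cases, and in 16 when adjusted over the list alone, with Hbe1 from 66.9 ± 24.0 to 0.0343 ± 0.0344. Ahsp, encoding the chaperone of alpha globin, fell by 3.45 ± 0.58, by 2.78 without fetal replicate 2 and by 2.59 without fetal replicate 2 and postnatal replicate 1. The erythroid set was lower by camera (median -2.16; adjusted p = 2.06e-04), with a median of -1.44 without those 2 libraries. That call was lost when the correlation was estimated (adjusted p = 0.475 with an estimated correlation). Only 4 lymphocyte markers could be tested: Cd4 and Lck rose by 1.64 ± 0.26 and 0.81 ± 0.22, and Cd3g and Cd5 fell by 1.13 ± 0.22 and 0.86 ± 0.20. The counts were also 2 and 2 when adjusted over the list alone. The 4 markers had a median of -0.03 and a mean of 0.11 (camera adjusted p = 0.950). In postnatal replicates 1 and 3 Cd3g stood at 0.0506 and 0.0341, under what 3 reads were worth there (0.152 and 0.102).

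**Figure D3:**
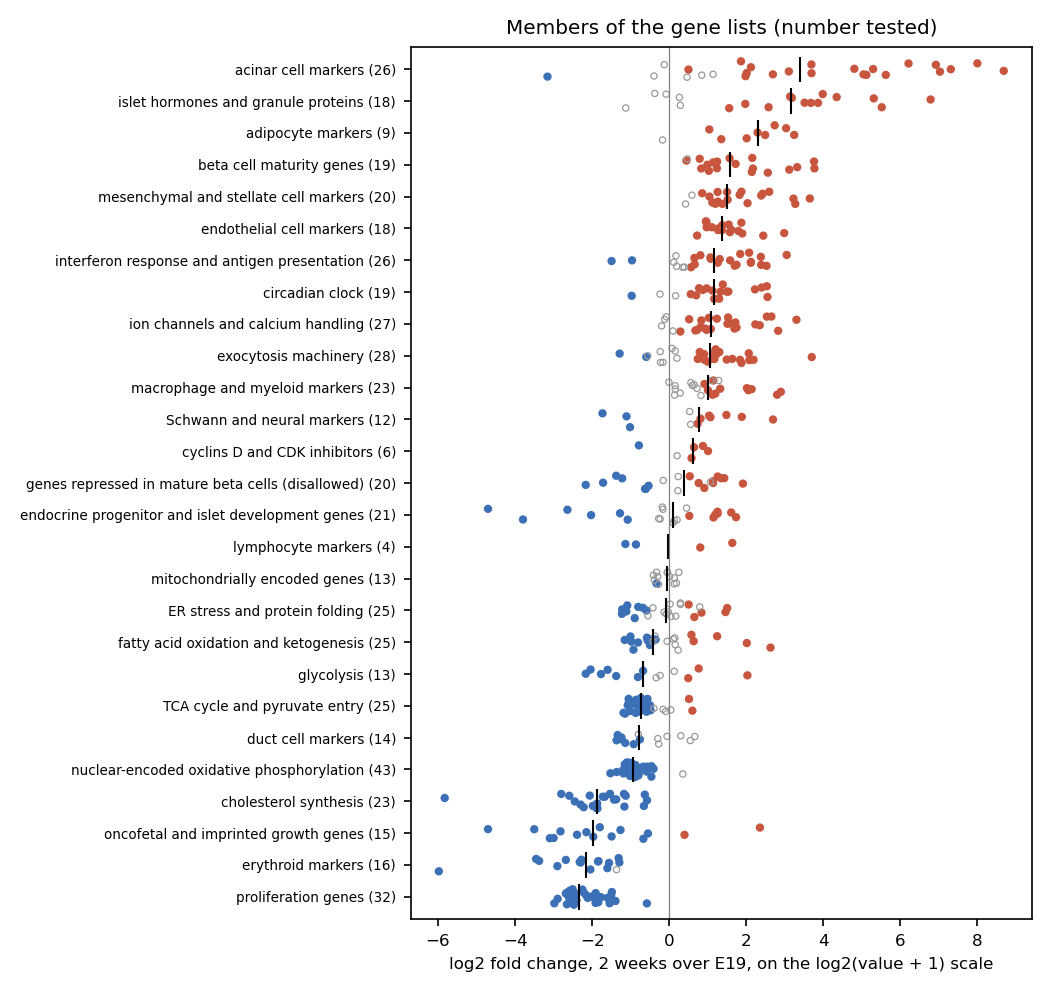
Log2 fold change (postnatal minus fetal) of every tested member of the 27 gene lists, with 1 point per gene, filled red where it rose, filled blue where it fell, open grey where it did not pass, and a black tick at the list median. All 32 proliferation genes and all 23 cholesterol synthesis genes lie below 0, and all 18 endothelial markers lie above it.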

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

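Leaving out fetal replicate 2 and postnatal replicate 1 together, and TMM factors computed without the acinar markers, were tests chosen after the results were seen; the other alternatives were planned. Of 24 alternatives, 22 tested single genes. Over these, the 58 named genes kept direction and call in 1262 cases and lost the call in 10 (all of them Mt-atp8), with no reversal, and 4 cases had no test. Over the 21 that gave list medians, these moved by less than the spread between replicates in 502 cases and by more in 65. With an estimated correlation, camera called 0 lists higher and 0 lower, against 11 and 6 with the preset correlation; at an unadjusted p under 0.05 it found 1 higher and 1 lower. Estimated correlations within lists ranged from -0.04 to 0.885, and that option also lowers the degrees of freedom of the test. The oncofetal list, with the lowest estimate, lost its call as well (adjusted p = 0.307). Fry asks whether a list moves at all, whereas camera compares it with the other genes, so their counts answer different questions. Fry called 11 and 9. It lost the macrophage list (adjusted p = 0.0833) and added the cyclin list as higher (adjusted p = 0.00438) and the glycolysis (adjusted p = 1.79e-04), duct (adjusted p = 0.0181) and endocrine progenitor lists (adjusted p = 0.00636) as lower. The glycolysis list, uncalled in the main test (adjusted p = 0.0659), also passed camera under 6 alternatives, with adjusted p from 0.0157 to 0.0495. A pseudocount of 5, which shrinks the fold changes of low genes by construction, left 1115 genes at least 2-fold higher, and rescaling without the 20 highest genes left 995 at least 2-fold lower. Leaving out 1 library at a time gave 3252 to 4005 genes higher and 3634 to 4470 lower. Without the 2 libraries 3786 were higher and 4089 lower, 2224 and 1797 by at least 2-fold. The labelled age as a covariate gave 3082 and 3449. That covariate was 0 in the fetal libraries and in the library of week 2. With 1 library per week it cannot be separated from the replicate number or the acinar share. On the recovered reads, edgeR called 3878 higher and 4251 lower and DESeq2 4206 and 4160; edgeR shared 8040 and DESeq2 8000 of the 8152 calls. A filter 5 times as strict gave 3006 and 4032, and no filter 4207 and 4401. Depth limits genes near 3 reads, as for Hbe1 in the postnatal libraries.

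With the replicate number as a block, 3563 genes were higher and 3863 lower, and 7351 of the 8152 calls were shared; 11 lists were higher and 6 lower. The deviations of libraries with the same number from their group means correlated at -0.21, 0.10 and -0.25 for replicates 1, 2 and 3. They gave no sign of pairing by number, and fetal replicate 3 correlated best with postnatal replicate 1 (0.43). With 3 libraries per group these correlations constrain one another, so pairing is not excluded. Besides Mt-atp8 (adjusted p = 0.0892), the block ended no call of a named gene.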

Other observations

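The tests of the endocrine share, of Serpina6 and of carried-over RNA, and the gene groups described first, were chosen after the results they concern were seen, and the hepatocyte genes were listed after Afp and Serpina6 were seen but before their own values were. Genes with the symbol of a cytosolic ribosomal protein fell almost without exception: 76 of 77 tested genes fell and none rose. Their median log2 fold change was -1.05 (-0.81 after rescaling without the 20 highest genes, when 76 fell). The 77 include like-named genes such as Rps18l1, Rpl7l1 and Rpl10l, so they are not all separate ribosomal proteins. Rps6, a component of the small subunit, fell from 1772 ± 310 to 738 ± 152 scaled CPM (mean ± SD, n = 3; log2 fold change -1.27 ± 0.22 SE), and Rpl29, of the large subunit, from 592 ± 93.3 to 275 ± 41.3 (-1.10 ± 0.16). Many ribosomal protein genes have processed pseudogenes that can share their reads.

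Of 22 tested immediate early and inflammatory genes, 11 rose and 2 fell, with a median of 0.98. Cxcl1 went from 5.33 ± 3.84 to 157 ± 94.1 (4.60 ± 0.59), Ccl2 from 2.64 ± 1.75 to 75.7 ± 47.5 (4.24 ± 0.58), and the cytokine gene Il6 rose by 3.60 ± 0.48. Nr4a1, Nfkbia, Atf3, Ier3, Dusp1 and Junb rose by 2.16 ± 0.40, 1.83 ± 0.29, 1.62 ± 0.42, 1.59 ± 0.32, 1.42 ± 0.30 and 1.21 ± 0.31. Fos stood at 619 ± 25.4 and 614 ± 230 and did not pass, and Jun and Jund fell by 0.57 ± 0.19 and 0.60 ± 0.10. After rescaling without the 20 highest genes 11 rose and 1 fell, as the Jun call ended (-0.33 ± 0.23; adjusted p = 0.240). In the same libraries the macrophage, mesenchymal and endothelial markers had medians of 1.01, 1.51 and 1.38. By age label, the postnatal library of week 2 had 4.07% of its reads in hormones and 48.7% in acinar markers, that of week 3 had 6.47% and 27.5%, and that of week 4 had 11.0% and 24.1%, with 1 library each. The heat shock gene Hspa8 and LOC680121 had nearly equal values in every library, 2039 and 2096 in postnatal replicate 1 for example, and are not separate measurements if the counting shared their reads.

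Of the 10 ways to split the 6 libraries into 3 and 3, 1, the real one, called as many as 8152 genes; the highest other split called 0 by limma, with 14 to 396 genes at an unadjusted p under 0.05. Every other split mixes fetal and postnatal libraries, so the difference between the groups adds to its spread and few calls follow from that. The splits are also too few for a share under 0.05, so no conclusion is drawn from them.

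Hormone and maturity genes rose together. A larger endocrine share of the RNA that raises all endocrine genes alike was tested with 18 pan-endocrine genes (14 of them also in a fixed list), of which 15 rose and 1 fell, with a median of 1.68 and an upper quartile of 3.00. The median of 7 hormone genes (Ins1, Ins2, Iapp, Gcg, Sst, Ppy and Pyy) was 4.35, above that quartile, as were 6 of the 7. With Ghrl, which counts in the hormone share and did not pass, the median of 8 was 4.17 and 6 of 8 lay above. The pan-endocrine genes themselves ranged from -0.91 (Vgf) to 3.87 (Pcsk1n), the latter near the 3.99 of Ins2. Any expression of these genes outside endocrine cells would lower their rise, so the test cannot decide whether a larger share explains the hormone rise. The median of the 19 maturity genes was 1.57, below the upper quartile of the pan-endocrine genes. A larger endocrine share is therefore not excluded for the list. Above the quartile lay 4 of them (Glp1r, Ucn3, Mafa and Cltrn). That 5 of the 18 pan-endocrine genes also lay above it follows from how a quartile is set, so the 2 counts are not compared. The rises of these 4, up to 3.78 for Glp1r, stayed under the 3.87 of Pcsk1n and so within the range of the pan-endocrine genes. Developmental age itself stays open and untested.

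Afp fell, but its fetal mean rests on fetal replicate 2. The median ratio of 21 other hepatocyte genes in that library over the mean of fetal replicates 1 and 3 was 83.8 (quartiles 28.0 and 175), with Alb at 2892 against 16.9 and 6.17 and Afp itself at a ratio of 37.7, which is consistent with liver tissue in that preparation. One of the 21 genes is also in the duct list. The Serpina6 ratio was 2.40, below the lower quartile, but some of the 21 genes lie below their own quartile by construction. Serpina1 was one of them, at 2.05, so the ratio cannot decide whether liver tissue supplied the fetal level of Serpina6. Serpina6 stood at 361 in fetal replicate 2 and at 94.1 and 207 in fetal replicates 1 and 3. A developmental difference stays open for Serpina6, and was not tested.

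The late acinar genes Cpb1, Cela2a, Ctrc, Prss1 and Zg16 were higher in fetal replicate 2 than in fetal replicates 1 and 3, but not all digestive enzyme genes were. If postnatal RNA or reads had been carried into it, postnatal genes of other cell types would show a similar excess there. The genes tested were at least 20 in postnatal replicate 3, under 1% of that level in fetal replicate 1 and higher in postnatal replicate 3 than in the acinar-rich postnatal replicate 1, without the acinar markers. Of 8 such genes, 100% reached a limit of 0.474% of the postnatal level in fetal replicate 2, set well below the median excess of 5 acinar markers (1.89%), and 1 of 8 did in fetal replicate 3. With genes chosen by fetal replicate 3 in place of 1, 14 of 14 reached their limit of 0.335% in fetal replicate 2 and 5 of 14 in fetal replicate 1, but 6 genes are in both sets. The 8 genes included Ppy, Ca3 and Il6, with a median excess of 1.65%. Postnatal RNA in that preparation may account for the pattern. Liver tissue, whose transcripts were high in the same library, was not tested as a source of these 8 genes. Against these libraries as its source stand 2 trypsinogen genes, whose close copies make single values uncertain. Try5 was 0.121 in fetal replicate 2, below fetal replicates 1 and 3 (0.276 and 0.216), where the acinar excess would add 12.1 from postnatal replicate 1 or 3.95 from postnatal replicate 2. LOC683849 was 2.57, between fetal replicates 1 and 3 (1.38 and 5.86), where it would add 9.54 from postnatal replicate 3. A more advanced state of that preparation stays open and untested.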
